A study of Lactiplantibacillus plantarum with 6 samples.

How the data were processed

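RNA of Lactiplantibacillus plantarum was sequenced from 6 libraries, 2 each from cells in MRS, in MRS set to pH 5.5 with HCl and in MRS set to pH 5.5 with lactic acid, at 30 °C from a starting optical density of 0.05, per the labels' protocols. RNA was isolated with an RNeasy kit and libraries were made with a TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, Trimmomatic and Bowtie 1.1.1. The counting tool, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Values of overlapping genes and of near-identical copies such as transposases are therefore uncertain, since their reads could be shared, and neighbouring genes of the fatty acid cluster overlap by a few bases.

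The deposited table gives RPKM, read numbers divided by the coding length in kilobases and by a denominator of each library, for 2570 coding regions, computed by the authors, with a column for each library. Rows carry coordinates, lp_ locus tags and product names. The index numbers run to 3062, and 492 of them are not in the table used here. Gene names are the locus tags and products of the table, since the reference at hand describes another assembly and was not used for names; coordinates are those of the table. Of the region lengths, 99.96% are multiples of 3, so lengths are coding lengths. In 300 regions the product is a hypothetical protein.

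Each RPKM value multiplied by its coding length was a whole multiple of a step per library, for 100% of 15420 values within 0.01 of a read, so read numbers were recovered. The denominators came to 8511213 to 11085445 and the reads over listed regions to 15679738 to 22005758, 1.83 to 2.04 reads per unit of denominator, so the denominator is not the sum of the listed reads. That ratio was 1.84 and 1.83 in MRS, 2.04 and 2.04 in HCl and 2.01 and 2.02 in lactic acid, so the deposited scaling places the acid libraries higher than a scaling to listed reads would. The 10 most abundant genes took 13.4% to 17.3% of the reads of a library and the top 100 took 49.3% to 54.2%. Under 10 reads were found for 0.74% to 1.25% of genes, and 3 to 6 genes per library were at 0. For a coding region of 1000 bases, 3 reads, the limit that a count of 0 allows, correspond to 0.271 to 0.352 RPKM; this covers counting error only. Where a gene had at least 100 reads, the variance between replicates was a median of 13.3 times the counting variance in MRS, 40.3 in HCl and 103.4 in lactic acid, so differences between libraries, not read numbers, limited the precision.

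The groups were taken from the labels, and all choices of tests, gene lists and the rule for named genes were made before the data were examined, except where the text says otherwise. Genes with a mean RPKM of at least 5 over the 6 libraries were tested (2528; 42 were left out). A single model with a coefficient per group was fitted to log2(RPKM + 1) with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3, with no further scaling, and the 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. Every adjusted p of a gene comes from this limma model. A pseudocount of 1 understates the change of genes with low values. The plan named a count test for a table of raw counts; the table held RPKM, so the limma test on log2 values was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and to draw figures.

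Gene lists were written as product patterns and symbols: F1Fo-ATPase, lactate interconversion and transport, glycolysis, pyruvate dissipation, citrate, malate and fumarate metabolism, chaperones and Clp proteases (cold shock proteins included), alkaline shock proteins, fatty acid biosynthesis, cyclopropane fatty acid synthases, lipoteichoic acid D-alanylation, peptidoglycan synthesis, polysaccharide biosynthesis, ribosomal proteins, aminoacyl-tRNA synthetases, pyrimidine, purine, arginine, aromatic with histidine and branched-chain amino acid biosynthesis, cysteine and methionine metabolism, amino acid decarboxylation, peptide and amino acid transport, PTS sugar transport, compatible solutes with potassium and sodium transport, manganese and iron transport, oxidative stress and thiol redox, SOS and DNA repair, bacteriocins, prophage, transposases and two-component systems. After the product names of the table had been read and before any test, 65 members missed by the patterns were added and 29 accidental matches were dropped. Lists with at least 5 tested members (27 of 30) were tested with camera in limma with a preset correlation of 0.01, which compares a list with the other genes; p-values were adjusted over the 81 list tests. Of these, 22 passed with the preset correlation and 0 with a correlation estimated from the libraries. That estimate rests on 6 libraries in 3 groups and is imprecise. With it even the fatty acid list, with medians 4.09 (HCl) and 4.75 (lactic acid) above that of all genes, had a camera adjusted p of 0.851. Not passing it therefore does not tell lists apart, and it leaves the calls with the preset correlation unchecked.

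Genes are named by a fixed rule. Among genes past the threshold with a mean RPKM of at least 20, the 2 libraries of a group both above the 2 of the other, and a product that names a function, the 12 largest rises and the 12 largest falls were named in each comparison, filled up to 5 per direction by the smallest p where fewer passed. Products that say only membrane, extracellular, cell surface or lipoprotein were taken as naming no function. All members of the F1Fo-ATPase and lactate lists were named whatever their p, and in each other list described 1 to 4 members with the smallest p. Genes called without a named function were 156 of 753 in HCl, 96 of 405 in lactic acid and 1 of 9 between the acids.

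The pipeline was tested on simulated data drawn from the real libraries' means and spread, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of the 4-fold changes 100% were recovered in each comparison. Noise was drawn independently for each library, with a common dispersion for all genes of a group, so recovery in the real data can be lower. LarA (lp_0104), for example, was 3.99-fold higher in lactic acid than in HCl and did not pass (limma adjusted p = 0.0545). Of the 2-fold changes 61% were recovered for HCl against MRS, 54% for lactic acid against MRS and 51% for lactic acid against HCl. In the same order, 0 of 161, 11 of 165 and 16 of 167 calls were false, with 2505, 2504 and 2531 genes tested. In 10 simulations with no change there were 0 false calls. Correlations of 2 comparisons that share the MRS libraries were set beside 100 simulations of unchanged groups. Alternatives were a pseudocount of 0.1 or 10, no filter or a filter at 50 RPKM, median-ratio factors, cyclic loess, a fit of the 4 libraries compared, eBayes without a trend, a minimum of 1 on the log2 scale, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the recovered reads, rescaling to the reads over listed regions, list tests with cyclic loess and lists exactly as first written.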

Results

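Transcript levels were measured by RNA sequencing in Lactiplantibacillus plantarum, a lactic acid bacterium of fermented food and of the gut, under 3 conditions with 2 libraries each. Cells were grown in MRS, a rich medium for lactobacilli, in MRS set to pH 5.5 with HCl, or in MRS set to pH 5.5 with lactic acid, the organism's own main fermentation product. The pH of the control medium and the growth phase at harvest were not given in the sources used here, so a difference between an acid and MRS may include a difference in growth phase. The labels give 4 h of treatment where the series design text gives 3 h. The table held RPKM for 2570 coding regions, 2554 on the chromosome and 16 on 2 plasmids, and 2528 were tested. Values are mean RPKM ± SD with n = 2 libraries per group, and fold changes are on the log2(RPKM + 1) scale. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

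Reads recovered over the listed coding regions came to 15679738 and 20286959 in the MRS libraries, 22005758 and 20288229 in the HCl libraries and 17561679 and 20084422 in the lactic acid libraries, with a median of 1105 to 1760 reads per gene. Across genes, log2 values of the 2 libraries of a group correlated at r = 0.995 in MRS, 0.993 in HCl and 0.979 in lactic acid (genes are not independent replicates). The lactic acid pair was the most spread, with 7.5% of genes differing over 2-fold between its libraries against 0.4% in each of the other groups. Lactic acid replicate 1 correlated more closely with HCl replicate 1 (r = 0.987) than with its own partner, and lactic acid replicate 2 correlated at 0.982 with HCl replicate 2.

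The comparison of HCl at pH 5.5 with MRS asked which transcripts change when the medium is acidified with a strong acid. A chromosomal cluster of fatty acid biosynthesis genes rose 21.0-fold to 48.2-fold. It runs from lp_1670 to lp_1682 (chromosome, 1522732 to 1532621) and holds 13 coding regions, among them the subunits of acetyl-CoA carboxylase, which makes malonyl-CoA, and the enzymes of the elongation cycle. The hydroxymyristoyl-ACP dehydratase gene lp_1677 went from 112 ± 9.06 RPKM in MRS to 5487 ± 1222 in HCl (log2 5.59, SE 0.25, limma adjusted p = 5.29e-05), and the acyl carrier protein gene lp_1672 from 431 ± 87.3 to 12300 ± 3475. Of 22 tested members of the fatty acid list, 12 rose and none fell (12 and 0 adjusted over the list alone). All 12 lie in this cluster. Its phosphopantetheinyltransferase gene lp_1682 is not in the list. The list ranked above the other genes by camera in limma (adjusted p = 0.000388, and 0.851 with an estimated correlation).

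**Figure D1:**
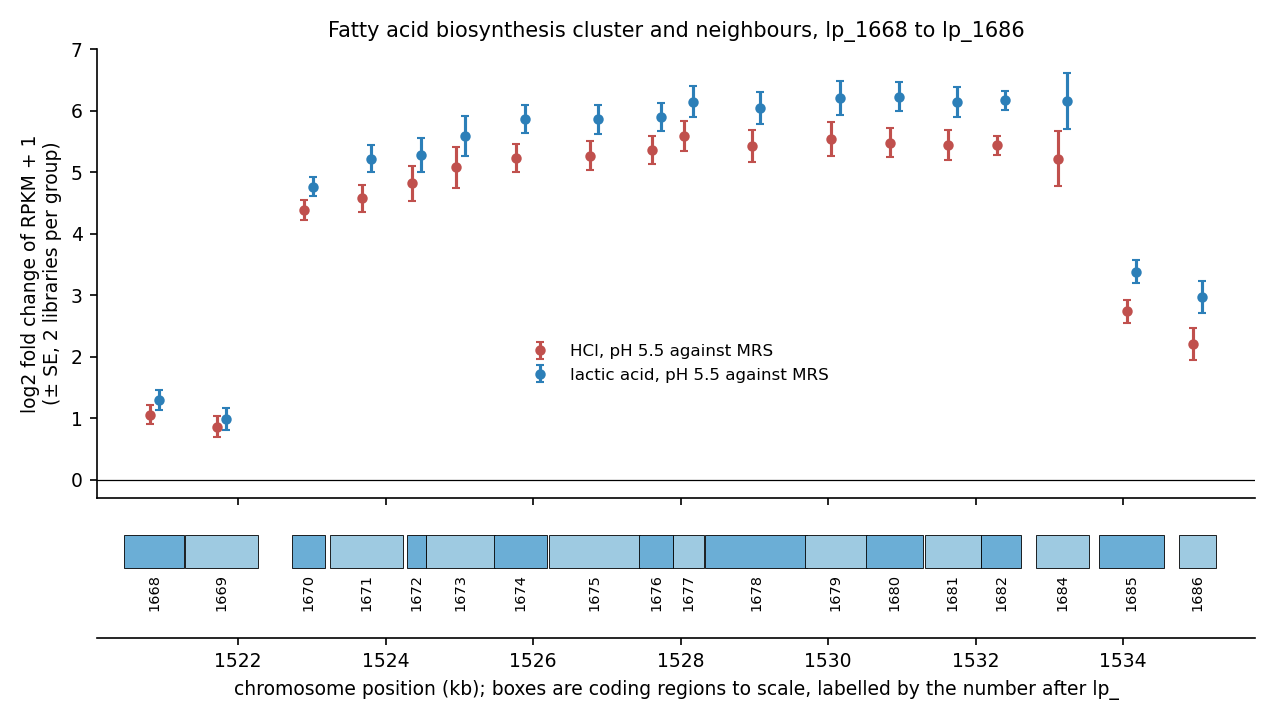
Log2 fold change of RPKM + 1 against MRS for the 18 tested neighbouring genes lp_1668 to lp_1686, placed by chromosome position in kb; points are fitted values for HCl and lactic acid, bars are ± SE from 2 libraries per group, and boxes are coding regions to scale. The 13 genes lp_1670 to lp_1682 lie between 4.39 and 5.59 in HCl and between 4.77 and 6.23 in lactic acid.

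The deepest falls in HCl included cold shock proteins, small RNA-binding chaperones, and a few abundant ribosomal protein genes. Cold shock gene lp_1160 (CspP; chromosome, 1058875 to 1059075) was 9.61-fold lower in HCl, from 43820 ± 15890 to 4471 ± 1063 RPKM (adjusted p = 0.00603), and lp_0997 (CspC) fell from 99880 ± 2694 to 27310 ± 1808 RPKM. CspL (lp_0031) was 2.02-fold lower. In the same list of chaperones and Clp proteases, ClpL (lp_3583), a chaperone ATPase, rose 2.32-fold. Of its 26 members 2 rose and 3 fell (1 and 3 adjusted over the list alone), and the 3 that fell were these cold shock genes. The list's median was 0.11 and its mean −0.12, and camera ranked it below other genes (adjusted p = 0.0216, and 0.851 with an estimated correlation). After cyclic loess scaling the list's p was 0.425. Among ribosomal proteins, L33 (lp_1569) was 6.03-fold, L19 (lp_1640) 4.65-fold, L31 (lp_0512) 3.75-fold and L32 (lp_1535a) 2.47-fold lower. Of 57 ribosomal protein genes 14 rose and 12 fell (16 and 15 adjusted over the list alone). Their median was 0.26, which was −0.14 relative to all genes and 0.13 after cyclic loess, so the direction of the family depended on the scaling; camera gave adjusted p = 0.00375 downward, 0.0781 with median-ratio factors, 0.821 with cyclic loess and 0.851 with an estimated correlation.

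Other genes with a named function fell more than 3-fold in HCl. The bacteriocin transport gene lp_3301 was 6.01-fold lower (330.5 ± 4.36 to 55.2 ± 15.9 RPKM), the Spx-type regulator lp_0836, of a family that binds RNA polymerase, 5.78-fold (2936 ± 196 to 508 ± 46.8), the phosphoglycerate mutase family gene lp_3170 5.39-fold, the TetR family regulator lp_1153 4.29-fold and the stress-responsive regulator lp_0126 4.04-fold. The acetyltransferase gene lp_2526 was 3.41-fold lower. Fructose-bisphosphate aldolase (lp_0330), which splits the glycolytic hexose, was 3.15-fold lower, at 32320 ± 514 against 10400 ± 2327 RPKM (adjusted p = 0.0146), and glucose-6-phosphate isomerase (lp_2502) 1.57-fold (lost with a filter at 50 RPKM and with eBayes without a trend). These were the 2 of 9 glycolysis genes that fell, and none rose (0 and 1 adjusted over the list alone; camera adjusted p = 0.0726, 0.0165 with the list as first written and 0.851 with an estimated correlation). The glycolysis list leaves out 10 of the 18 matches of its pattern as first written, the phosphoglycerate mutase family gene lp_3170 among them. Serine O-acetyltransferase lp_0254 and the cystathionine lyase lp_0255, both of cysteine synthesis, were 2.66-fold and 2.36-fold lower. In the wider cysteine and methionine list of 21 genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with the methionine transporter permease lp_1745 2.81-fold and the methionine synthase lp_1856 2.88-fold higher, the last lost with cyclic loess.

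Genes that handle protons and lactate moved by smaller amounts. All 8 genes of the F1Fo-ATPase, which can export protons at the cost of ATP (lp_2363 to lp_2370; chromosome, 2134274 to 2140720), had positive values between 0.39 and 0.64 on the log2 scale, and the alpha (lp_2366), beta (lp_2364) and gamma (lp_2365) subunit genes rose by 1.52-fold, 1.43-fold and 1.5-fold. The other members, lp_2363, lp_2367, lp_2368, lp_2369 and lp_2370, did not pass (4 of 8 rose adjusted over the list alone; camera adjusted p = 0.264). The list's median of 0.59 was 0.2 relative to all genes and 0.48 with cyclic loess. The 3 gene calls were lost with median-ratio factors and with cyclic loess, while camera passed with cyclic loess (adjusted p = 0.0311, against 0.851 with an estimated correlation in the deposited scaling). Of the 14 lactate genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.264). The L-lactate dehydrogenase gene lp_0537 (chromosome, 485467 to 486429), whose enzyme converts pyruvate to L-lactate, fell from 2674 ± 120 to 1211 ± 52.5 RPKM (2.21-fold lower, adjusted p = 0.00401). LarB (lp_0105), LarC (lp_0106, N-terminal part) and LarE (lp_0109), which build the cofactor of lactate racemase, rose by 2.28-fold, 2.73-fold and 1.72-fold. Dehydrogenase genes lp_1082, lp_1101, lp_1245 and lp_2150 rose by 1.63-fold to 2.42-fold. D-lactate dehydrogenase lp_2057 (12390 ± 177 and 12600 ± 1387 RPKM), the racemase LarA (lp_0104, log2 0.74), lp_0107, lp_0350, lp_1814 and lp_2349 did not pass. With cyclic loess LarB, LarE, lp_1082, lp_1101, lp_1245 and lp_2150 were not called, and with median-ratio factors LarE, lp_1101 and lp_2150 were not.

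Some genes of amino acid synthesis rose in HCl from low levels in MRS. In the aromatic, histidine and branched-chain list 20 of 32 genes rose and none fell (25 and 0 adjusted over the list alone), with imidazole glycerol phosphate synthase lp_2554 at 15.8 ± 0.845 against 50.5 ± 3.2 RPKM (3.06-fold), phosphoribosyl-AMP cyclohydrolase lp_2553 2.60-fold and 3-dehydroquinate dehydratase lp_3493 2.10-fold higher. The first 2 belong to histidine synthesis and the last to the shikimate pathway. In the arginine list 7 of 11 rose (10 adjusted over the list alone), with lp_0531 and lp_0532 at 2.31-fold and 2.27-fold. Camera gave adjusted p = 0.000662 for the aromatic list and 0.0399 for the arginine list, both 0.851 with an estimated correlation. The medians relative to all genes, 0.71 and 0.73, shrank to 0.24 and 0.25 with cyclic loess, where camera gave 0.171 and 0.127 and lp_2553, lp_3493, lp_0531 and lp_0532 were no longer called. Values in HCl were higher as a whole toward low expression. The median log2 fold change was 1.05, 0.68 and 0.47 in the lowest 3 eighths of genes by mean RPKM (5.3 to 125.5). These 5 named genes lie there. In the highest eighth the median was 0.17. Between the 2 lactic acid libraries (replicate 2 minus replicate 1) the medians were 0.55 in the lowest eighth and 0 in the highest.

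Some genes of transport, redox and repair also rose. The manganese transport gene lp_2992 (chromosome) rose 5.09-fold, from 69.2 ± 8.65 to 355 ± 9.64 RPKM (adjusted p = 0.000341), and the Nramp transporter MntH (lp_1295) 2.25-fold. In all, 5 of 14 manganese and iron genes rose (5 adjusted over the list alone; camera adjusted p = 0.241). In the list of compatible solutes, potassium and sodium 11 of 20 rose (11 adjusted over the list alone; camera adjusted p = 0.0728, 0.0312 with cyclic loess and 0.851 with an estimated correlation), among them the Na(+)/H(+) antiporter lp_3338 (3.52-fold) and the glycine betaine transport genes lp_0368 (2.42-fold) and lp_3324 (1.82-fold, lost with median-ratio factors). NADH oxidase lp_3449, which reduces oxygen with NADH, rose 2.91-fold, glutathione reductase lp_0369 1.93-fold and NADH peroxidase lp_2544 2.01-fold, the last lost with median-ratio factors and with cyclic loess. In all, 7 of 25 redox genes rose (8 adjusted over the list alone; camera adjusted p = 0.231). In the SOS and DNA repair list 13 of 18 rose (13 adjusted over the list alone), with the excinuclease subunits lp_0773 and lp_0772 at 2.0-fold and 2.13-fold and the polymerase V gene lp_3023 at 2.0-fold. Camera gave adjusted p = 0.0216 for SOS and DNA repair, 0.052 with median-ratio factors, 0.000649 with cyclic loess, 0.0637 with the list as first written and 0.851 with an estimated correlation. Pyruvate oxidase lp_0852 rose 2.56-fold and formate C-acetyltransferase lp_3313 was 1.48-fold lower, in a pyruvate list where 3 of 21 rose and 1 fell (2 and 1 adjusted over the list alone). The response regulator lp_0131 and the sensor lp_0130, neighbours by tag, rose 4.39-fold and 4.66-fold from 10.9 ± 1.96 and 6.53 ± 1.95 RPKM; 7 of 27 two-component genes rose and 2 fell (9 and 2 adjusted over the list alone).

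In the remaining lists for HCl, 21 of 45 peptide and amino acid transport genes rose and 1 fell (23 and 2 adjusted over the list alone), with the branched-chain amino acid transporters lp_3466 at 3.48-fold and lp_0399 at 2.99-fold. Of 48 sugar phosphotransferase (PTS) genes 22 rose and 1 fell (22 and 1 adjusted over the list alone), with lp_2097 at 1.75-fold (lost with median-ratio factors) and lp_3240 at 2.37-fold (lost with cyclic loess). Camera passed for this list with median-ratio factors (adjusted p = 0.0347, against 0.0989), and with cyclic loess for aminoacyl-tRNA synthetases (0.0441 against 0.29) and, downward, transposases (0.0311 against 0.258). Each of these 3 lists had adjusted p = 0.851 with an estimated correlation in the deposited scaling. Of 24 aminoacyl-tRNA synthetase genes 12 rose and 1 fell (15 and 1 adjusted over the list alone): the histidine enzyme lp_2561 rose 3.62-fold, the alanine enzyme lp_2277 1.57-fold (lost with median-ratio factors) and the lysine enzyme lp_0550 was 1.58-fold lower. Adenylosuccinate synthase lp_3270 (1.74-fold lower), adenylosuccinate lyase lp_3269 (1.59-fold) and GMP synthase lp_0914 (1.64-fold) were the 3 of 16 purine genes that fell, and none rose (0 and 3 adjusted over the list alone). Cyclopropane fatty acid synthase lp_3174 rose 1.55-fold, lost with median-ratio factors and cyclic loess, and lp_1696 did not pass (log2 0.61; 1 of 2 rose, 2 adjusted over the list alone). Of 22 citrate, malate and fumarate genes 6 rose (6 adjusted over the list alone), the fumarate reductase lp_1425 by 2.62-fold. Bacteriocin genes gave 2 up and 1 down of 16, pyrimidine synthesis 3 up and 1 down of 14, polysaccharide synthesis 1 up of 7, prophage 4 up of 14, alkaline shock proteins 1 up of 4 and transposases 1 down of 6 (adjusted over the list alone 1 and 1, 5 and 1, 0 and 0, 4 and 0, 1 and 0, and 0 and 1). No gene passed in the lists of peptidoglycan synthesis (17), lipoteichoic acid D-alanylation (6) or amino acid decarboxylation (1), over all genes or adjusted over the list alone.

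Over all genes, limma called 753 of 2528 genes between HCl and MRS, 620 higher and 133 lower, and 372 of them changed at least 2-fold (312 higher, 60 lower). The median log2 fold change of all tested genes was 0.39 in the deposited scaling and 0 with median-ratio factors, where 323 genes were higher and 314 lower (184 and 274 with cyclic loess); 141 higher and 131 lower genes were called in all 3 scalings. The count fell to 38 and 40 without MRS replicates 1 and 2 and to 52 and 59 without HCl replicates 1 and 2, and rose to 1444 and 1449 without lactic acid replicates 1 and 2, which share the estimate of the spread. Of 76 named genes past the threshold, 21 stayed past it without either MRS library in turn, 28 without HCl replicate 1 or replicate 2, and 20 in every setting tried: lp_1670 to lp_1682, lp_2992, lp_3449, lp_0512, lp_0836, lp_0997, lp_1640 and lp_2526.

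**Figure D2:**
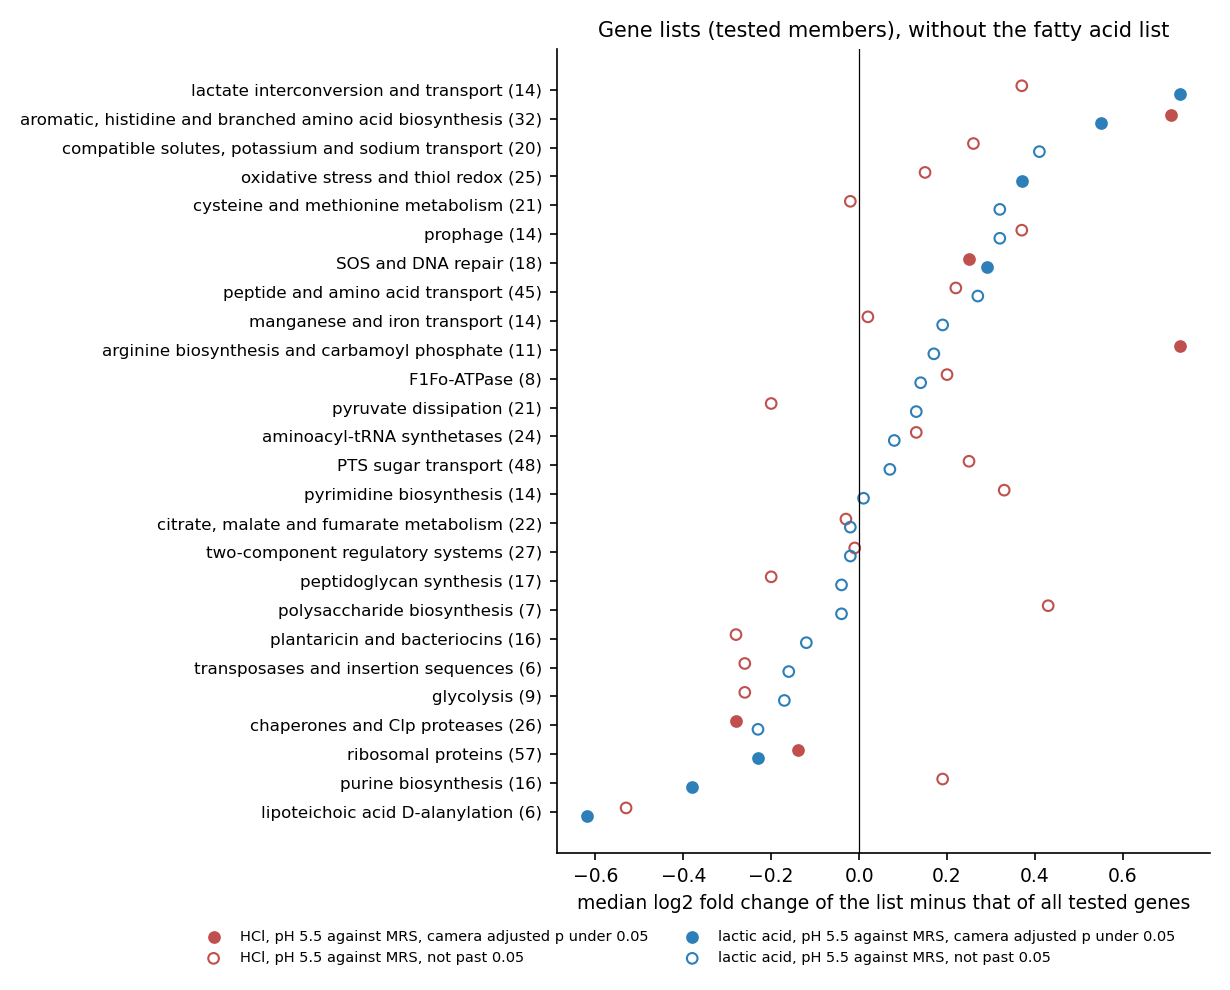
Median log2 fold change of each gene list minus the median of all tested genes, for HCl against MRS and lactic acid against MRS, with tested members in brackets; filled points passed camera at an adjusted p under 0.05 with the preset correlation, and the fatty acid list (4.09 and 4.75) is left out for scale. With cyclic loess the medians of 7 of 27 lists in HCl and of 5 of 27 in lactic acid changed sign, among them ribosomal proteins (0.13), polysaccharide (−0.28) and purine (−0.06) in HCl and glycolysis (0.06) in lactic acid.

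The comparison of lactic acid at pH 5.5 with MRS asked for the response to acidification with the organism's own product. The same cluster lp_1670 to lp_1682 rose, here by 27.2-fold to 74.9-fold. The acetyl-CoA carboxylase subunit gene lp_1680 (chromosome, 1530521 to 1531291) went from 83.3 ± 1.81 to 6467 ± 1964 RPKM (log2 6.23, SE 0.23, adjusted p = 2.63e-05). In the fatty acid list 12 of 22 rose and none fell (13 and 2 adjusted over the list alone; camera adjusted p = 4.74e-05, and 0.851 with an estimated correlation). The genes of lactate racemization rose: LarA (lp_0104; chromosome, 93016 to 94290), the enzyme that interconverts L- and D-lactate, from 11.6 ± 2.43 to 82.6 ± 15.9 RPKM (6.66-fold, adjusted p = 0.002), LarB (lp_0105) 6.75-fold, the 2 parts of LarC (lp_0106, lp_0107) 6.36-fold and 5.62-fold, and LarE (lp_0109) 2.59-fold. L-lactate dehydrogenase lp_0537 fell from 2674 ± 120 to 671 ± 14.4 RPKM, 3.98-fold lower (adjusted p = 0.000242).

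Across the 14 lactate genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0182, and 0.851 with an estimated correlation). Beside the 5 lar genes, lp_1101, lp_1245 and lp_2150 rose by 2.17-fold, 2.37-fold and 1.72-fold. Not past the threshold were lp_1082 (log2 0.84), the L-lactate transporter lp_1814 (0.70), D-lactate dehydrogenase lp_2057 (0.32), lp_2349 (0.12) and lp_0350 (−0.20). None of the 8 F1Fo-ATPase genes lp_2363 to lp_2370 passed in lactic acid, over all genes or adjusted over the list alone, with values of 0.10 to 0.54 (camera adjusted p = 0.34).

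The deepest fall in lactic acid was that of the ammonium transport gene lp_0349 (chromosome, 318549 to 319865), 12.8-fold lower at 97.2 ± 0.861 against 1256 ± 100.5 RPKM in MRS (log2 −3.67, SE 0.16, adjusted p = 3.11e-05). Among purine genes, adenylosuccinate synthase lp_3270 and GMP reductase lp_3271 were each 4.55-fold lower, adenylosuccinate lyase lp_3269 2.86-fold, IMP dehydrogenase lp_3194 1.90-fold and GMP synthase lp_0914 1.61-fold. These enzymes lead from IMP to AMP and between IMP and GMP. In the purine list, which leaves out lp_3271, 4 of 16 fell and none rose (0 and 4 adjusted over the list alone; camera adjusted p = 0.00262, and 0.851 with an estimated correlation), and the median relative to all genes was −0.38. Aspartate ammonia-lyase lp_2830, which releases ammonium from aspartate, was 3.69-fold lower (2059 ± 153 to 558 ± 61.2 RPKM), the sugar transporter lp_2514 4.23-fold and the glutamine transporter gene lp_0803 2.59-fold.

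Several genes fell in lactic acid as they had in HCl. Cold shock gene lp_1160 was 7.54-fold and lp_0997 2.66-fold lower, bacteriocin transport gene lp_3301 6.17-fold, ribosomal proteins lp_1569, lp_1640 and lp_0512 4.09-fold, 3.06-fold and 2.33-fold, the regulators lp_0836 and lp_0126 3.57-fold and 3.18-fold, and lp_3170 3.51-fold. Of 57 ribosomal protein genes 4 fell and none rose (0 and 4 adjusted over the list alone; median −0.23 relative to all genes and −0.01 with cyclic loess). Camera gave the ribosomal list adjusted p = 0.0181, 0.539 with cyclic loess and 0.851 with an estimated correlation. Among chaperones and Clp proteases 3 of 26 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.104), with ClpL (lp_3583) at 3.30-fold and ClpE (lp_1269) at 1.84-fold higher. None of the 6 genes of lipoteichoic acid D-alanylation passed, over all genes or adjusted over the list alone; all 6 values were negative (−0.75 to −0.10; lp_2017 at −0.48), and camera gave adjusted p = 0.0216, 0.128 with cyclic loess and 0.851 with an estimated correlation.

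Manganese transport gene lp_2992 rose 7.25-fold in lactic acid, to 507 ± 35.9 RPKM, and MntH (lp_1295) 2.30-fold (4 of 14 rose, 5 adjusted over the list alone). NADH oxidase lp_3449 rose 4.13-fold, NADH peroxidase lp_2544 3.44-fold and glutathione reductase lp_0369 1.74-fold, and 7 of 25 redox genes rose (10 adjusted over the list alone; camera adjusted p = 0.0181, and 0.851 with an estimated correlation). Excinuclease genes lp_0773 (1.78-fold) and lp_2109 (2.14-fold, lost with cyclic loess) were among 7 of 18 SOS and repair genes that rose (12 adjusted over the list alone; camera adjusted p = 0.0217, 0.0721 with the list as first written and 0.851 with an estimated correlation). In the aromatic, histidine and branched-chain list 4 of 32 rose (1 adjusted over the list alone; camera adjusted p = 0.00399, and 0.851 with an estimated correlation), with the aminotransferase lp_2390 at 2.17-fold and lp_2038 at 2.75-fold from 2.94 ± 1.19 RPKM, the last lost with a pseudocount of 10 and with rescaling to listed reads. Pyruvate oxidase lp_0852 rose 3.24-fold, the pyruvate dehydrogenase subunit gene lp_2154 1.75-fold and acetolactate decarboxylase lp_2030 1.57-fold (lost with median-ratio factors and cyclic loess), among 6 of 21 pyruvate genes that rose (9 up and 3 down adjusted over the list alone).

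Of 20 compatible solute and ion genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with lp_3338 at 2.78-fold, lp_3324 at 2.24-fold and lp_0368 at 1.78-fold. Of 45 peptide and amino acid transport genes 15 rose and 4 fell (16 and 4 adjusted over the list alone), among them the oligopeptide transporter genes lp_1262, lp_1263 and lp_1264 at 2.73-fold, 2.77-fold and 2.44-fold. Methionine transporter genes lp_1745 and lp_1746 rose 3.57-fold and 2.73-fold (the last lost with cyclic loess) and serine O-acetyltransferase lp_0254 was 2.45-fold lower, in a list where 8 of 21 rose and 2 fell (8 and 2 adjusted over the list alone). Both cyclopropane fatty acid synthase genes rose, lp_1696 2.42-fold and lp_3174 1.60-fold (2 adjusted over the list alone), the last lost with median-ratio factors and cyclic loess. In sugar phosphotransferase genes 8 of 48 rose (8 adjusted over the list alone; lp_0575 1.91-fold), in aminoacyl-tRNA synthetases 6 of 24 (8; lp_0609 1.60-fold, lost with median-ratio factors), and in two-component systems 2 of 27 rose and 3 fell (3 and 6; lp_0131 3.32-fold higher). Bacteriocin, pyrimidine and transposase genes gave 1 fall each of 16, 14 and 6, alkaline shock 1 rise of 4, citrate, malate and fumarate 2 rises of 22 and peptidoglycan 1 rise of 17 (adjusted over the list alone 1, 0, 1, 1, 1 and 0). No gene passed in glycolysis (9), polysaccharide (7), arginine (11), prophage (14) or decarboxylation (1), over all genes or adjusted over the list alone. The glycolysis list leaves out the phosphoglycerate mutase family gene lp_3170, which was 3.51-fold lower.

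Limma called 405 of 2528 genes between lactic acid and MRS, 280 higher and 125 lower, with 221 changed at least 2-fold (142 higher, 79 lower). The median log2 fold change of all genes was 0.25, and with median-ratio factors, which bring it to 0, 256 genes were higher and 281 lower (255 and 293 with cyclic loess); 184 higher and 125 lower genes were called in all 3 scalings. The median of all genes was 0.42 without lactic acid replicate 1 and 0.08 without replicate 2. With the 4 libraries compared alone the count of called genes was 222. Of the named genes lp_0369, lp_0609, lp_0914, lp_2030, lp_2038, lp_2150 and lp_3174 were not called there. The count fell to 50 and 53 without MRS replicates 1 and 2 and to 220 and 223 without HCl replicates 1 and 2, and rose to 1269 without lactic acid replicate 1 (566 without replicate 2). Of 68 named genes past the threshold 27 and 30 stayed past it without MRS replicates 1 and 2, and 25 in every setting tried, among them lp_1670 to lp_1682, lp_0104, lp_0105, lp_0106, lp_0349, lp_0537, lp_3270, lp_2830, lp_2992 and lp_3583.

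The direct comparison of lactic acid with HCl at the same pH of 5.5 asked which transcripts depended on the acid used. The ammonium transport gene lp_0349 was 7.72-fold lower, at 97.2 ± 0.861 RPKM in lactic acid and 761 ± 107.7 in HCl (log2 −2.95, SE 0.16, adjusted p = 0.00146). Adenylosuccinate synthase lp_3270 (2.62-fold), xanthine permease lp_2710 (2.33-fold), aspartate ammonia-lyase lp_2830 (2.27-fold), phosphate transporter permease lp_0748 (2.5-fold) and the cation transporting ATPases lp_0567 (2.60-fold) and lp_0124 (2.05-fold) were also lower, each at adjusted p = 0.0442. The extracellular transglycosylase lp_3014, with a domain that binds peptidoglycan, was 2.53-fold higher at 1625 ± 288 against 638 ± 30.0 RPKM. The hypothetical gene lp_2987, named after its values were seen, was 2.51-fold higher. Against MRS lp_2987 was lower in both acids, 5.37-fold in HCl and 2.14-fold in lactic acid.

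**Figure D3:**
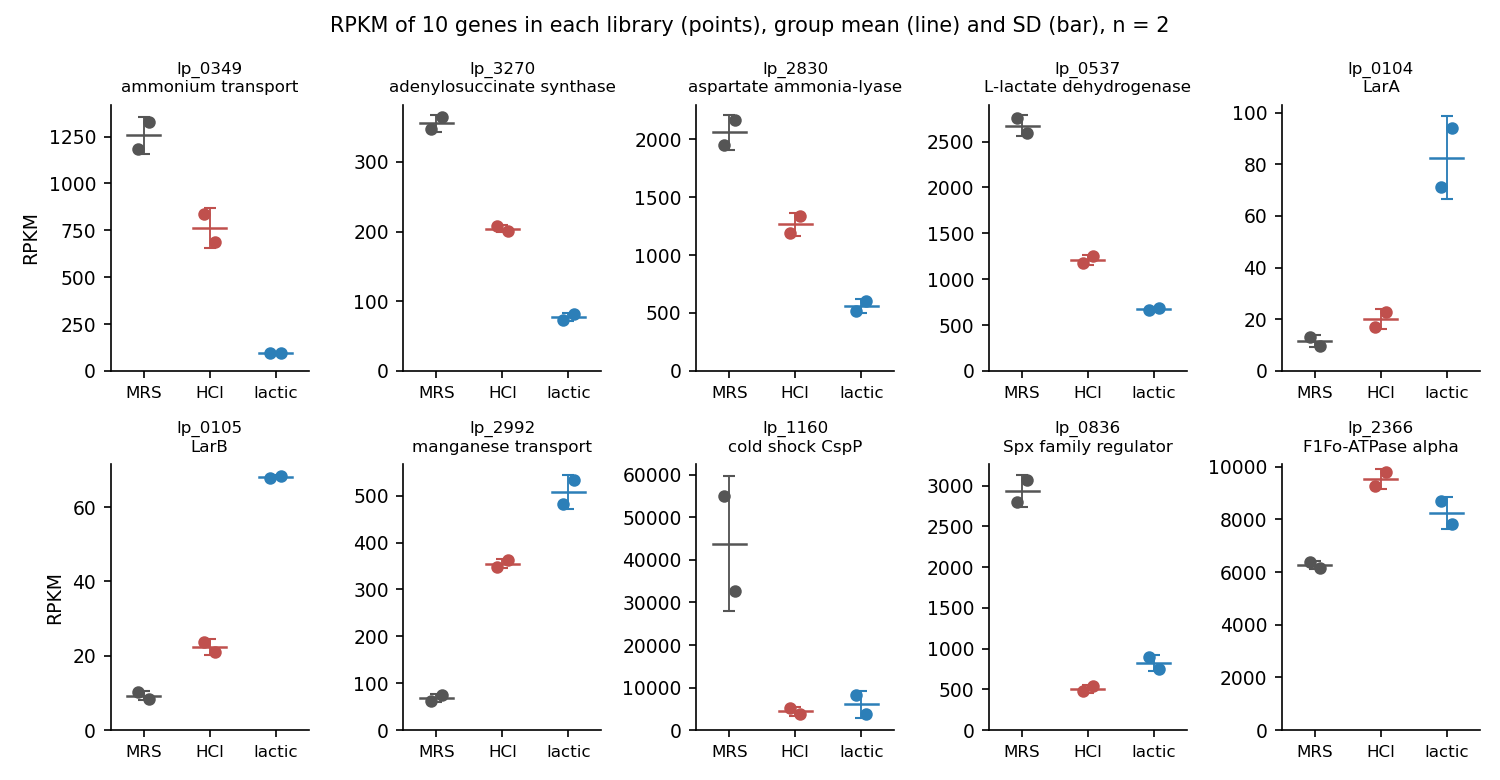
RPKM on a linear axis from 0 for 10 genes in each of the 6 libraries; points are libraries, lines are group means and bars are SD with n = 2. The ammonium transport gene lp_0349 stands at 97.2 in lactic acid against 761 in HCl, and LarA (lp_0104) at 82.6 against 20.

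The lactate racemization genes were higher in lactic acid than in HCl by log2 2.0 for LarA (lp_0104, adjusted p = 0.0545), 1.57 for LarB (lp_0105, 0.0624), 1.22 and 1.71 for the parts of LarC (lp_0106 and lp_0107, both 0.137) and 0.59 for LarE (lp_0109, 0.262), none past the threshold over all genes. With median-ratio factors and with cyclic loess LarA (0.0202 and 0.0137), LarB (0.0295 and 0.0339) and both parts of LarC (0.0295 and 0.0137 for lp_0106, 0.0363 and 0.0212 for lp_0107) passed. L-lactate dehydrogenase lp_0537 was lower by log2 −0.85 (adjusted p = 0.0724, and 0.0456 with cyclic loess). The other lactate genes ran from −0.89 (lp_0350) through lp_1082, lp_2349, lp_2150, lp_1814, lp_1101 and lp_2057 to 0.42 (lp_1245). Adjusted over the list alone 4 of the 14 lactate genes were higher and 2 lower. Camera placed the lactate list higher in lactic acid (adjusted p = 0.000833, and 0.851 with an estimated correlation).

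No single gene passed in the other lists except lp_3270, but camera placed 7 more lists apart, each with adjusted p = 0.851 with an estimated correlation. The purine list ranked lower (median −0.55 relative to all genes, adjusted p = 0.000753; 0 higher and 1 lower, and 0 and 2 adjusted over the list alone), with lp_3269 at −0.85. The fatty acid list ranked higher (median 0.55 relative to all genes, camera adjusted p = 0.000753), with lp_1680 at 0.75. Of its 22 values 7 were negative, all outside the cluster lp_1670 to lp_1682. The 10 members outside it ran from −0.65 (lp_0362) to 0.38 (lp_0522). Glycolysis (0.31, adjusted p = 0.0388), pyruvate (0.14, 0.0216) and redox genes (0.16, 0.0216) ranked higher, with aldolase lp_0330 at 1.08, glucose-6-phosphate isomerase lp_2502 at 0.58, pyruvate dehydrogenase lp_2154 at 0.84 and NADH peroxidase lp_2544 at 0.78. Polysaccharide (−0.49, adjusted p = 0.029) and aromatic, histidine and branched-chain genes (−0.37, 0.0216) ranked lower, with lp_1317 at −0.38, while lp_2390 of the last list stood at 0.74. With cyclic loess the calls were lost for glycolysis (limma camera adjusted p = 0.114), polysaccharide (0.58), redox (0.0647) and the aromatic list (0.58, where its median turned to 0.04), and with median-ratio factors that for glycolysis (0.25). Gained were cysteine and methionine metabolism with cyclic loess (0.00147 against 0.168, higher) and arginine synthesis with median-ratio factors (0.0347 against 0.0808, lower), both 0.851 with an estimated correlation in the deposited scaling. Adjusted over the list alone, 3 peptide and amino acid transport genes were lower, with the glutamine transporter lp_0803 and its neighbour lp_0802 both at −0.74, 1 pyruvate gene, 1 chaperone gene and 1 cyclopropane synthase gene were higher, and no gene of any other list passed.

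Limma called 9 of 2528 genes between the acids, 2 higher and 7 lower in lactic acid, while 440 passed an unadjusted p of 0.05. The median log2 fold change was −0.13, and with median-ratio factors 16 genes were higher and 13 lower (12 and 10 with cyclic loess); lp_0567 and lp_0124 were not called with median-ratio factors, nor lp_0567 with cyclic loess. The count was 1, the gene lp_0349, with the 4 libraries compared alone, with eBayes without a trend and without any 1 of MRS replicates 1 and 2 and HCl replicates 1 and 2, and 301 and 516 without lactic acid replicates 1 and 2.

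The responses to the 2 acids were compared across genes, with lp_1670 to lp_1682 at the upper end and lp_1160, lp_1569 and lp_3301 at the lower end of both. Called in the same direction in both were 292 genes, 212 higher and 80 lower, where independent lists of these sizes would share 68.7 and 6.58, and simulated unchanged groups with the same controls shared 0.01 and 0.02 on average. With median-ratio factors 333 genes were shared, 143 higher and 190 lower, so which direction held more genes depended on the scaling. The phosphate transporter permease lp_0748 was the single gene called in opposite directions, higher in HCl (log2 0.67) and lower in lactic acid (−0.66); with median-ratio factors and with cyclic loess its value in HCl did not pass (adjusted p = 0.284 and 0.229). The log2 fold changes correlated at r = 0.847 across genes, against 0.499 (range 0.449 to 0.541) in 100 simulations of unchanged groups sharing the control libraries, and the covariance was 0.472 against 0.033 simulated, a difference of 0.439. The simulations drew noise independently for each library. They leave out that the replicate differences of HCl and lactic acid correlated at r = 0.75, which may add to the excess. The 2 control libraries could not be split into groups of 2, so part of the excess may also come from the shared controls beyond the simulated noise. The count of shared genes was 31 and 30 without MRS replicates 1 and 2, 47 and 54 without HCl replicates 1 and 2 and 951 without lactic acid replicate 1 (415 without replicate 2).

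**Figure D4:**
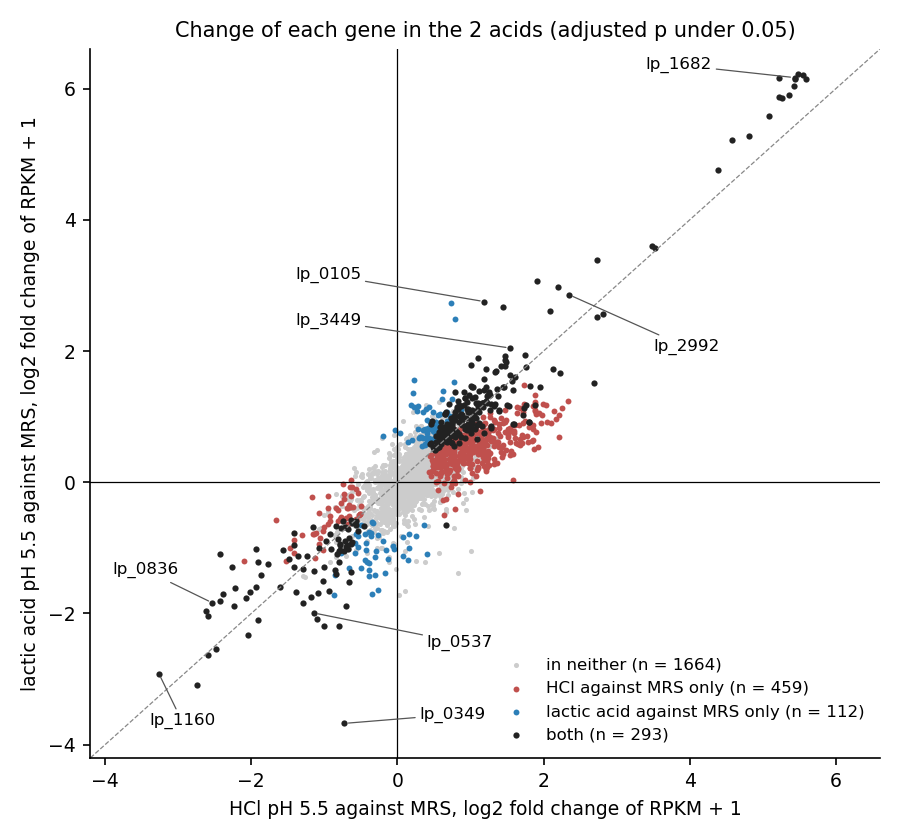
Log2 fold change of RPKM + 1 in HCl (horizontal) and in lactic acid (vertical) against MRS for 2528 genes, with colours for an adjusted p under 0.05 in neither, one or both comparisons and a dashed line of equal change. The fatty acid gene cluster stands at the upper right, and lp_0349 lies at −0.73 in HCl and −3.67 in lactic acid.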

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

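The test of a single scaling factor, the simulation of a constant background, the split of the acid libraries by replicate number, the search for day or batch labels and both tests of the fatty acid gene cluster were chosen after the results had been seen.

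In 9 genes the effect of lactic acid at pH 5.5 differed from that of HCl at pH 5.5 by a direct test, on the log2 scale as lactic acid minus HCl, from the same limma model with 2 libraries per group. The ammonium transport gene lp_0349 differed by −2.95 (adjusted p = 0.00146). The other 8 stood at adjusted p = 0.0442: adenylosuccinate synthase lp_3270 at −1.39, the cation transporting ATPase lp_0567 at −1.38, the phosphate transporter permease lp_0748 at −1.32, the xanthine permease lp_2710 at −1.22, aspartate ammonia-lyase lp_2830 at −1.18, the cation transporting ATPase lp_0124 at −1.04, the hypothetical gene lp_2987 at 1.33 and the transglycosylase lp_3014 at 1.34. In each of them both libraries of an acid lay above both of the other. Over the 17 other settings the values ran from −1.47 to −1.25 for lp_3270, −1.29 to −1.04 for lp_2830 and 1.16 to 1.52 for lp_3014. Without any 1 of MRS replicates 1 and 2 and HCl replicates 1 and 2, lp_0349 alone stayed past the threshold.

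Genes with low expression were higher in HCl than in MRS: the median log2 fold change was 1.05 in the lowest eighth of genes and 0.17 in the highest. Lactic acid against MRS gave 0.49 and 0.09. Replicate 2 minus replicate 1 gave 0.55 and 0 in lactic acid, 0.21 and 0.03 in HCl and 0.14 and −0.02 in MRS. Such a trend therefore also stood between libraries of the same condition. A single wrong scaling factor per library moves all genes alike, which would not by itself part the medians of 1.05 and 0.17. Their difference of 0.88 (95% bootstrap interval over genes 0.76 to 1.01) restates the pattern and is no separate test. The interval leaves out the spread between libraries. A constant background such as genomic DNA added to every gene is argued against as the whole cause. Of the 316 lowest genes 8.2% (exact binomial interval 5.4% to 11.8%, against a bound of 5% set beforehand) lay below the median increment of 13.1 RPKM in both HCl libraries. In 1000 simulations of that background with the replicate spread of HCl, the share was at most 0.95%. Noise around a common increment, drawn separately in each library, is argued against by a Spearman correlation of 0.79 (0.73 to 0.83). That correlation was taken across these genes between the increments of the 2 replicate numbers. Noise shared by the 2 libraries of a group, or a common fold change, could also raise this correlation, so it decides nothing about those. A smaller constant background beside another cause, a background that differs between genes, and a response of the cells to HCl, stay open and were not tested.

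The difference between replicates 2 and 1 ran alike across genes in HCl and in lactic acid (r = 0.75). A trend with expression level is argued against as the whole cause, since r was 0.73 (0.69 to 0.76) after a loess trend was taken out. An exchange of the replicates 2 of the 2 acids would make the differences run opposite, so the split planned for it (0 genes in limma, adjusted, and 0 at an unadjusted p under 0.05) decides nothing here. An exchange of an HCl library with the lactic acid library of the other number would make them run alike, and it stays open: the split by number gave 0 genes where the labels gave 9 (limma, adjusted), but 610 against 440 at an unadjusted p under 0.05. A shared day or batch of the libraries with the same number stays open, since 0 day or batch labels were given and the numbers alone do not pair the samples. A biological difference between cultures was not tested.

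The fatty acid genes lp_1670 to lp_1682 rose in both acids, with median log2 fold changes of 5.36 in HCl and 5.90 in lactic acid. The rise stood in all 3 scalings, with a lowest median of 4.97 over the 2 other scalings and both acids. This could be foreseen and is no separate test. Median-ratio factors moved the median of all genes only from 0.39 to 0 in HCl and from 0.25 to 0 in lactic acid. Reads shared with other fatty acid genes are argued against by the 10 other tested members of the list. Their median was 0.30 in HCl (members from −0.42 to 0.38) and 0.01 in lactic acid (members from −1.07 to 0.70), with 0 called in either (limma, adjusted) and 3 in each at an unadjusted p under 0.05. A response of these genes to acidification is a hypothesis consistent with these values, found and tested on the same data.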

How the results depend on the processing

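Chosen after seeing the data were limma-voom on recovered reads, rescaling to reads over listed regions, list tests with cyclic loess and lists exactly as first written. The number of genes called moved with the libraries more than with any other setting. For HCl against MRS (753), a filter at 50 RPKM gave 392 genes (fewer genes tested), cyclic loess 458, the 4 libraries compared 1444, a minimum log2 change of 1 372, rescaling to listed reads 434, and leaving out a library 38 to 1449. For lactic acid against MRS (405), the 4 libraries compared gave 222, a minimum log2 change of 1 221, and leaving out a library 50 to 1269. For lactic acid against HCl (9), median-ratio factors gave 29, cyclic loess 22, the 4 libraries compared 1, eBayes without a trend 1, and leaving out a library 1 to 516. The shared count (292) ran from 30 to 951 without a library. List tests passed in 22 of 81, and in 0 with an estimated correlation (21 with median-ratio factors, 17 with cyclic loess, 20 of 75 with lists as first written). With the replicate number as a block the counts were 1290, 947 and 74 genes and 23 lists; replicate differences correlated at 0.2 (MRS and HCl), 0.3 (MRS and lactic acid) and 0.75 (HCl and lactic acid), but 2 pairs do not show that the numbers pair the samples. A lone library left in a group was assumed to vary like the other groups. The causes were not tested, except that the lactic acid pair holds the widest spread (SD 0.52 on the log2 scale against 0.25 in MRS and 0.28 in HCl) and enters the shared estimate. Voom on recovered reads gave 766, 410 and 11 genes. Of the named genes past the threshold, 20 of 76, 25 of 68 and 1 of 8 kept direction and call in every setting, 35, 34 and 0 lost the call only without a library and 21, 9 and 7 in another setting; none past the threshold changed direction. Genes not past the threshold, and named by rule, that changed sign were few. In HCl, cyclic loess gave lp_0104 −0.15, lp_0350 −0.46, lp_2057 −0.08 and lp_2349 −0.06, median-ratio factors lp_2057 −0.37, lp_2349 −0.29 and lp_2363 −0.01, and rescaling to listed reads lp_2057 −0.13 and lp_2349 −0.05. In lactic acid against MRS, median-ratio factors gave lp_2349 −0.13, lp_2369 −0.15 and lp_2370 −0.03, rescaling lp_2349 −0.02 and lp_2369 −0.03, and cyclic loess lp_2349 0.00. Between the acids cyclic loess gave lp_1082 0.16. Without a library in turn, values crossed 0 for lp_2057 (−0.09 to 0.13) and lp_2349 (−0.13 to 0.33) in HCl, lp_2349 (−0.28 to 0.51), lp_2369 (−0.52 to 0.73) and lp_2370 (−0.12 to 0.56) in lactic acid, and lp_1814 (−0.07 to 0.46), lp_2150 (−0.10 to 0.26) and lp_2349 (−0.38 to 0.41) between the acids. The test planned for raw counts was not run, since the table held RPKM. Depth limits little here, with a median of 1105 to 1760 reads per gene.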

Other observations

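The search for runs of neighbouring genes was chosen after the results had been seen.

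Neighbouring genes, in the order of the table, were searched for runs of 3 or more called in the same direction in both acids and in all 3 scalings (81 genes higher and 80 lower). There were 6 such runs, where 1000 shuffles of gene order gave 0.19 on average and 2 at most. Shuffles do not keep neighbours together, and overlapping neighbours could share reads, so they show that calls cluster and not why. The longest held 18 genes, lp_1668 to lp_1686 (chromosome, 1520457 to 1535262), which are the fatty acid cluster and neighbours on both sides. Before it lie the short-chain dehydrogenase lp_1668 (log2 1.06 in HCl, 1.29 in lactic acid) and the AraC family regulator lp_1669 (0.86, 0.99). After it lie the membrane protein lp_1684 (5.22, 6.16), the LysR family regulator lp_1685 (2.74, 3.38) and the acyl-CoA hydrolase lp_1686 (2.20, 2.97). A run of 4 rose at lp_3176 to lp_3179 (2834878 to 2837420), where the membrane protein lp_3177 (2.73, 2.51) and the extracellular protein lp_3178 (2.81, 2.57) stand beside the serine/threonine protein kinase lp_3176 (0.89, 0.88). The glycine betaine transport genes lp_0367 and lp_0368 and glutathione reductase lp_0369 rose together (334512 to 338419; medians 1.19 and 0.80).

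The other 3 runs fell in both acids. The purine genes lp_3269, lp_3270 and lp_3271 (2908776 to 2912700) had medians of −0.80 in HCl and −2.19 in lactic acid. The run lp_2512 to lp_2514 (2243860 to 2246214), a membrane protein, a hypothetical protein and a sugar transporter, had medians of −1.10 and −1.75. Cell surface protein genes lp_3677 to lp_3679 (3295024 to 3297330) had medians of −1.61 and −1.59, with the CscB family gene lp_3679 at 700.3 RPKM in MRS, 134.9 in HCl and 226.9 in lactic acid.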
